A study of Homo sapiens with 8 samples.

How the data were processed

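Expression was measured on 8 arrays of the HG-U133 Plus 2.0 design, 1 for each RNA sample, from the human myeloma cell lines MM1S and OPM1 with and without Zalypsis. The labels put the arrays in 4 groups of 2. Nothing in the labels says that the arrays of a group came from separate cultures, so the p-values measure the spread between these arrays, which may be technical only. Per the labels' protocols, 100 ng of total RNA was amplified in a 2-cycle cDNA synthesis and labelled with biotin, and per the series' design text the arrays were scanned and analysed with the dChip software. The sources differ on the labelling: the sample protocols name GeneChip kits and the design text an Enzo BioArray kit, and neither says whether the lines were labelled together or how much poly-A control RNA was added. The version of dChip, its normalization between arrays and its probe model are not given in the sources used here.

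The deposited values are intensity values on a linear scale, 1 for each of 54675 probe sets and each array, as the authors' dChip analysis gave them. None was negative, the lowest value of an array lay between 0.54 and 0.92 and the highest between 16628 and 18317. Between 929 and 1027 values on each array were exactly 1. The median signal ranged from 23.0 to 24.8. No depth applies to arrays, and their number limits the precision.

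The values were kept as the authors normalized them and turned into log2(value + 32). A fold change on that scale understates the change of dim genes. The 62 control probe sets were kept out of the gene tests. Of the other probe sets, 41091 carried 1 gene symbol in the platform annotation, 1801 carried several and 11721 carried none in the table used here, and only those with 1 symbol were used. For 41037 of them the symbol was found through its gene identifier in a table of RefSeq genes of the assembly GRCh38.p14, from which also the span of each gene was taken. Where a gene had several probe sets, the one with the highest mean over the 8 arrays stood for it, which left 19775 genes. The 40% with the lowest mean, below a signal of 27.3, were left out, and 11865 genes were tested. No genome sequence was used here, and no positions are given. A gene that the naming rule lists is not reported here.

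Group means were compared with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a trend), with 1 mean per group and 1 shared spread over all 8 arrays, which left 4 residual degrees of freedom and an estimated prior of 17.0. The contrasts were Zalypsis against control in each line, the difference between the lines' responses (OPM1 minus MM1S) and untreated OPM1 against untreated MM1S. P-values were adjusted by the Benjamini-Hochberg method within a contrast, and a gene was called at an adjusted p under 0.05. Errors of log2 fold changes are standard errors, and signals are means ± SD of 2 arrays. The overlap of the lines' calls was set against the number that independent lists would share. These comparisons have no array in common.

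Before the data were examined, 34 gene lists were fixed, of which 30 had at least 5 tested members. They were tested with limma's camera at a preset correlation between genes of 0.01, with camera at an estimated correlation, and with fry, and adjusted over the lists of a contrast. Camera called 6 lists in MM1S, 3 in OPM1, 7 for the difference and 6 between the untreated lines. With an estimated correlation it called 0 in each, and fry called 10, 15, 11 and 10. Lists were described where camera called them, and 6 more, the BCL2 family and RNA polymerase II lists in MM1S and the p53 target, immediate early, plasma cell and replication lists in OPM1, were chosen for description after all results were seen. The genes named in the text follow a rule written before the data were examined: a few genes of interest whatever their values, the 8 largest rises and 8 largest falls in each line among called genes whose treated and control arrays did not overlap, up to 4 called members of each list described, the 6 largest called differences each way between the lines' responses and between the untreated lines, and the 6 genes risen and 6 fallen in both lines with the largest smaller change. Genes that mark sex were not eligible for naming. Outside that rule, JCHAIN and B-lineage markers such as EBF1, BACH2, MYB and SPIB were named after results were seen. Members of the 6 lists chosen late came in through that choice.

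The steps were tested on simulated data with the real means and spreads, in 20 draws per comparison with 200 of 11865 genes changed. A log2 change of 1 was called for 99.9% of the genes in MM1S and for 88.7% in the comparison of responses, and a log2 change of 0.5 for 48.1% and 15.1%. For OPM1 these shares were 99.9% and 49.6%, and for the untreated lines 99.9% and 50.8%. A log2 change of 2 was called for 100% in every comparison, and 0 calls had the wrong sign. False calls made up 6.88% of the calls in MM1S, 6.58% in OPM1, 6.61% for the difference and 6.23% between the untreated lines, above the nominal 5%. Of 2000 random lists, camera gave a p under 0.05 to 58, 57, 70 and 81 in the same order. The simulated genes varied independently, so this does not show how camera behaves on lists of correlated genes. Far fewer genes were changed than were called in the data, so the shares may not carry over.

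Alternatives were other pseudocounts, filters, normalizations between arrays, variance models and choices of probe set. A fit on only the arrays compared, a replicate block and leaving out each array in turn were also used. The authors' cutoff of a change over 2-fold was applied to the log2 values of the tested genes, not to the deposited intensities. A scaling of the OPM1 arrays by their poly-A control probe sets was added after the data were seen. The replicate numbers of the labels pair no samples by any stated source.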

Results

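Zalypsis is a compound of marine origin that binds DNA. Its effect on transcripts was measured in MM1S and OPM1, which are established cell lines of human multiple myeloma, a cancer of plasma cells. Each line gave 2 control arrays and 2 arrays of cells treated with Zalypsis at 5 nM, collected when 15 to 20% of the cells were dying. Arrays of the same group correlated at 0.988 to 0.993 across probe sets on the log2 scale, and arrays of different groups at 0.801 to 0.963. No pair shared more than 441 identical values.

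Some measures of RNA quality and labelling moved with the groups. The ratio of the 3' to the 5' probe set was 2.26 for GAPDH and 5.80 for ACTB on OPM1 control 1, against 0.963 to 1.06 and 1.78 to 2.62 on the other arrays. The 75th percentile of the signal was 77.5 and 78.7 on the treated OPM1 arrays and 101 to 115 elsewhere. The 4 poly-A control probe sets, which read bacterial transcripts added to a sample before labelling, had a geometric mean of 19.7 to 25.7 on the MM1S arrays. That is about the median signal of all probe sets (23.0 to 24.8), so MM1S values can show little of a change in these controls. That mean was 299.7 and 448 on the OPM1 controls and 1862 and 1349 on the treated OPM1 arrays. A 28S ribosomal RNA probe set rose from 1071 and 1327 to 11465 and 9325 in the same arrays (log2 3.12). Its rise was the largest of the 6 ribosomal RNA probe sets, and the other 28S sets rose by 1.16 and 1.08. By contrast, the geometric mean of the 9 hybridisation controls stayed between 1335 and 1968 on all arrays. Some transcripts typical of plasma cells, such as SDC1, were near background on the OPM1 arrays, as described with the untreated lines, and their cells are therefore called OPM1-labelled.

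**Figure D1:**
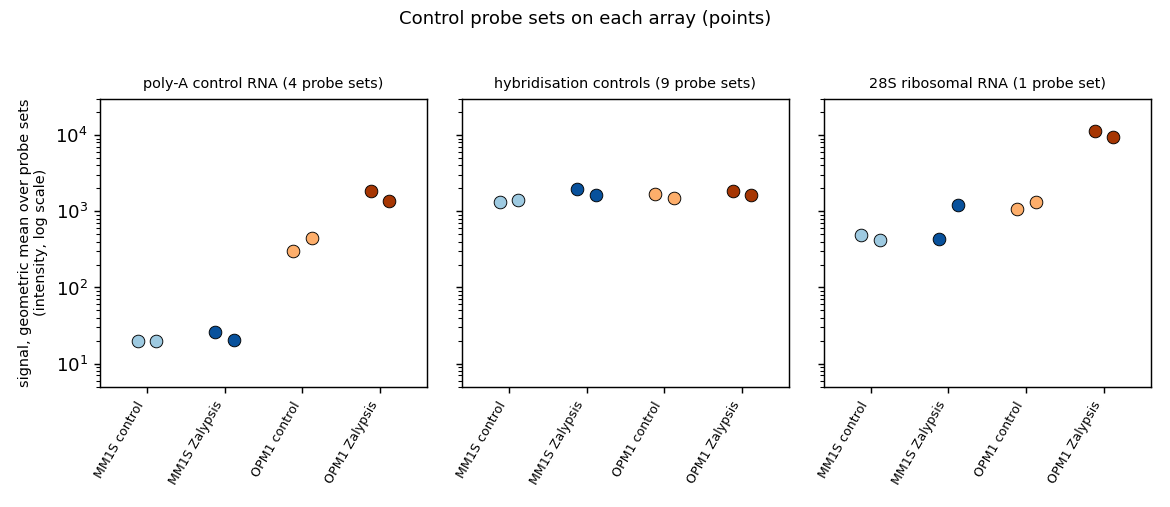
Signal of control probe sets on each array (log axis, intensity), as the geometric mean of 4 poly-A controls and of 9 hybridisation controls. The third panel shows 1 28S ribosomal RNA probe set, the one that rose most in OPM1-labelled cells. Each point is 1 array. Poly-A controls lie at 19.7 to 25.7 in MM1S and reach 1862 and 1349 in treated OPM1-labelled cells, where that 28S probe set reads 11465 and 9325.

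In MM1S, Zalypsis raised many p53 target genes and lowered MYC, with the deepest falls in CDK14 and STAG1. CDKN1A, which encodes the cell cycle inhibitor p21, rose from a signal of 906 ± 226 to 3502 ± 201 (SD, n = 2), a log2 change of 1.93 ± 0.16 (adjusted p = 2.5e-09). HEXIM1, which encodes an inhibitor of the elongation factor P-TEFb, rose from 360 ± 13.4 to 2277 ± 178, the largest rise by the naming rule (log2 2.56 ± 0.15). MYC fell from 3022 ± 58.5 to 679 ± 25.7 (log2 -2.10 ± 0.17, adjusted p = 1.6e-09). In all, 4457 of 11865 genes were called, 1950 higher and 2507 lower, and 1043 of them changed over 2-fold, 193 higher and 850 lower. Only 986 were higher without MM1S Zalypsis 1 and 1163 without MM1S control 2. Lower genes made up 56.2% of the calls, and 45.4% after quantile normalization.

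Other large rises in MM1S were those of SERTAD1 (log2 2.53), a regulator of CDK4, PLK2 (2.15), a stress-induced kinase, and TNFSF9 (2.15), the ligand of the receptor 4-1BB. MARCKSL1 (2.14), TNFRSF10D (1.99), a decoy receptor for TRAIL, and TENT5A (1.88) followed. The largest falls were in CDK14 (log2 -4.43), whose signal went from 1762 ± 121 to 51.0 ± 5.95, and in STAG1 (-4.11), a cohesin subunit, from 1015 ± 151 to 28.5 ± 2.53. TIAM1 (-3.73), DOCK4 (-3.68) and ELMO1 (-3.67), which act on the GTPase Rac, fell with FNDC3B (-3.67), FBXL7 (-3.64) and the kinase CAMK1D (-3.62). The adjusted p of these 14 genes lay at or below 7.6e-11 except for TNFSF9 (5.5e-10) and MARCKSL1 (1.7e-10).

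Of 34 tested p53 target genes, 25 rose and 3 fell (27 and 3 adjusted over the list alone), with a median log2 change of 1.03. Camera gave this list an adjusted p of 1.0e-11 (adjusted p = 0.937 with an estimated correlation). Besides CDKN1A and PLK2, DDB2 (log2 1.78) and TIGAR (1.65) rose. MDM2, which encodes a ubiquitin ligase, rose from 1765 ± 7.64 to 2510 ± 176 (log2 0.50 ± 0.15, adjusted p = 1.3e-02), a call that was lost without MM1S Zalypsis 1 (log2 0.43, adjusted p = 0.134). GDF15, a stress-induced cytokine gene, was too dim to be tested, at 15.5 ± 1.65 in control and 28.3 ± 1.75 in treated arrays. Immediate early genes rose as well, 13 of 24 against 2 that fell (13 and 3 over the list alone), with a median of 0.68 (camera adjusted p = 2.0e-04, adjusted p = 0.937 with an estimated correlation). IER2 (log2 1.77), NR4A1 (1.76) and JUNB (1.53) were among them, while MYC, which is on the list too, fell. NR4A1 was not called when probe sets shared between transcripts were left out (log2 0.017). Of 19 cholesterol synthesis genes 11 rose and 2 fell, the same over the list alone, with a median of 0.43 (camera adjusted p = 1.3e-03, adjusted p = 0.937 with an estimated correlation). STARD4 (log2 1.34), TM7SF2 (0.99), SC5D (1.34) and IDI1 (1.01) led them, the last 2 only with probe sets of the shared kind.

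Genes of the ATF4 and amino acid response fell in MM1S, 18 of 27 against 1 that rose (21 and 1 over the list alone), with a median log2 change of -0.55 (camera adjusted p = 1.9e-07, adjusted p = 0.937 with an estimated correlation). The cystine transporter gene SLC7A11 fell by 3.41 on the log2 scale, from 524 ± 101 to 20.5 ± 11.4, and CHAC1 by 3.04. PSAT1 (log2 -2.03) and SLC7A1 (-1.64) fell too. Of 34 nuclear transport genes 17 fell and 1 rose, the same over the list alone, with a median of -0.41 (camera adjusted p = 1.3e-03, adjusted p = 0.937 with an estimated correlation), among them IPO8 (-1.22), NUP93 (-1.09), NUP153 (-0.96) and NUP155 (-0.93). NUP153 was not called as the mean of its probe sets (log2 -0.24, adjusted p = 0.0813), 1 of which rose by 0.56. Of 28 plasma cell genes 11 fell and 0 rose (11 and 1 over the list alone), with a median of -0.26 (camera adjusted p = 0.0171, adjusted p = 0.937 with an estimated correlation). IRF4, a transcription factor on which myeloma cells depend, fell from 4383 ± 727 to 1012 ± 127 (log2 -2.08), with MEF2C (-1.91), IL6R (-0.99) and XBP1 (-0.91).

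Lists that camera did not call in MM1S held large single changes. In the BCL2 family, 5 of 14 genes rose and 1 fell, the same over the list alone (camera adjusted p = 0.259). BCL2 itself, which protects from apoptosis, fell from 660 ± 65.9 to 95.8 ± 18.9 (log2 -2.44), and PMAIP1, which promotes it, rose from 522 ± 35.1 to 1566 ± 23.3 (log2 1.53). BCL2L2 (log2 0.75) and BIK (0.48) rose too, but both calls were lost without MM1S Zalypsis 1 (adjusted p = 0.104 and 0.119) and in other settings. Of 38 genes of RNA polymerase II and the general transcription factors, 10 rose and 8 fell, the same over the list alone (camera adjusted p = 0.200). HEXIM1, CCNT1 (log2 0.90) and POLR2A (1.74), the largest subunit of the polymerase, were higher and GTF2E2 (-1.10) lower.

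**Figure D2:**
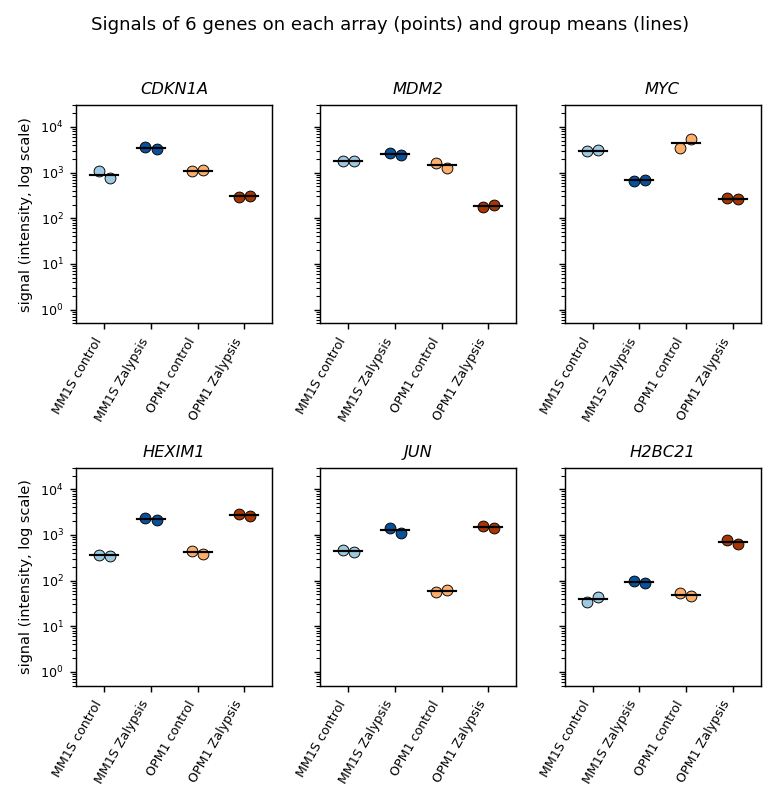
Signals (log axis, intensity) of CDKN1A, MDM2, MYC, HEXIM1, JUN and H2BC21 on each array. Points are arrays, 2 per group, and lines are group means. CDKN1A goes from 906 to 3502 in MM1S and from 1113 to 302 in OPM1-labelled cells, while HEXIM1 is higher after Zalypsis in both.

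In the OPM1-labelled cells, Zalypsis raised JUN, ATF3 and histone transcripts and lowered PAX5, MYC and CDKN1A. JUN rose from 59.3 ± 3.63 to 1485 ± 76.0 (SD, n = 2), a log2 change of 4.05 ± 0.16, and ATF3 from 49.0 ± 10.9 to 1098 ± 0.799 (3.81 ± 0.16). Both were also higher on the treated MM1S arrays, from a brighter start. There JUN went from 443 ± 22.0 to 1274 ± 228 and ATF3 from 489 ± 53.1 to 1137 ± 179. PAX5, which keeps B cells in their lineage, fell from 3219 ± 476 to 50.9 ± 19.7 (log2 -5.31 ± 0.15, adjusted p = 1.9e-16). CDKN1A fell from 1113 ± 37.2 to 302 ± 7.05 (log2 -1.78, adjusted p = 2.2e-09), MDM2 from 1448 ± 275 to 185 ± 9.60 (-2.76, adjusted p = 7.2e-13) and MYC from 4477 ± 1411 to 271 ± 3.41 (-3.86, adjusted p = 2.0e-14). In all, 7579 of 11865 genes were called, 3012 higher and 4567 lower, and 3528 changed over 2-fold, 901 higher and 2627 lower. Scaled by the poly-A controls, 10834 were called and 99.5% of them were lower. Lower genes made up 60.3% of the calls, and 45.4% after quantile normalization.

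The other large rises were those of C12orf57 (log2 3.53), ARRDC3 (3.34), TLCD2 (3.33), LINC00662 (3.24), the histone gene H2BC21 (3.18) and ID2 (3.12), an inhibitor of basic helix-loop-helix factors. A second probe set of LINC00662 went the opposite way (log2 -1.18). The other large falls were those of GBE1 (log2 -5.12), a glycogen branching enzyme, PIP4K2A (-4.81), CMSS1 (-4.80), the nuclear pore gene NDC1 (-4.80), ID3 (-4.77), MYCBP2 (-4.63) and RUBCNL (-4.60). ID3 went from 2399 ± 469 to 56.5 ± 8.88. The adjusted p of these 13 genes lay at or below 9.1e-14. GDF15 was dim here too, at 13.3 ± 3.34 in control and 15.5 ± 1.10 in treated arrays.

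Histone genes rose in the OPM1-labelled cells, 11 of 14 with 0 lower, the same over the list alone, and a median log2 change of 2.39 (camera adjusted p = 3.1e-06, adjusted p = 0.354 with an estimated correlation). H2BC21 rose from 49.2 ± 6.02 to 708 ± 88.3, and H2BC6 (log2 3.10), H2BC5 (3.07) and H2AC6 (2.85) rose with it. Of 34 nuclear transport genes, 29 fell and 3 rose, the same over the list alone, with a median of -1.68 (camera adjusted p = 1.1e-05, adjusted p = 0.984 with an estimated correlation). CSE1L (log2 -2.96), KPNA3 (-2.89), NUP205 (-2.67) and NUP88 (-2.61) fell most. Of 12 end joining genes, which repair DNA double-strand breaks, 11 fell and 0 rose, the same over the list alone, with a median of -1.22 (camera adjusted p = 9.5e-03, adjusted p = 0.984 with an estimated correlation). PRKDC (log2 -2.70), XRCC4 (-2.52) and XRCC5 (-2.22) fell, and so did DCLRE1C (-1.91), of which 2 other probe sets went up by 0.80 and 0.71 and whose mean over probe sets was not called (-0.28, adjusted p = 0.119). These groups moved on arrays whose ribosomal and poly-A control signals also rose, as given above. Scaled by the poly-A controls, the median of all genes moved from -0.07 to -1.42 and that of the 12 histone genes then tested was 0.75.

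The p53 target genes did not move together in the OPM1-labelled cells. Of 34 genes 8 rose and 10 fell (8 and 9 over the list alone), with a median log2 change of -0.10 (0.15 after quantile normalization) and a camera adjusted p of 0.739. TRIAP1 rose by 1.78, but not with the poly-A scaling (-0.30), and CYFIP2 fell by 2.58. Of 24 immediate early genes 9 rose and 7 fell, the same over the list alone (camera adjusted p = 0.104, and 0.0467 without OPM1 control 1, 6.5e-03 with a replicate block and 7.7e-03 with the poly-A scaling), with JUN, ATF3 and KLF6 (log2 2.05, and 0.11 with the poly-A scaling) higher and MYC lower. Of 28 plasma cell genes 17 fell and 4 rose, the same over the list alone (median -0.97, camera adjusted p = 0.0668). That list was called after quantile normalization (camera adjusted p = 0.0242), without OPM1 control 1 (0.0467) and with a replicate block (6.5e-03). For both lists the block value came from camera on the t-statistics of the fit, not on expression values, so the test changed as well. IKZF1 (log2 -3.39), IKZF3 (-3.16), POU2AF1 (-3.10) and MEF2C (-2.94), all transcriptional regulators of lymphocytes, were among the fallen plasma cell genes. Of 39 replication and S-phase genes 22 fell and 7 rose, the same over the list alone (median -0.53, camera adjusted p = 0.181). POLA1 (log2 -2.67), CDC45 (-2.66), MCM3 (-2.46) and GINS1 (-2.14) fell.

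**Figure D3:**
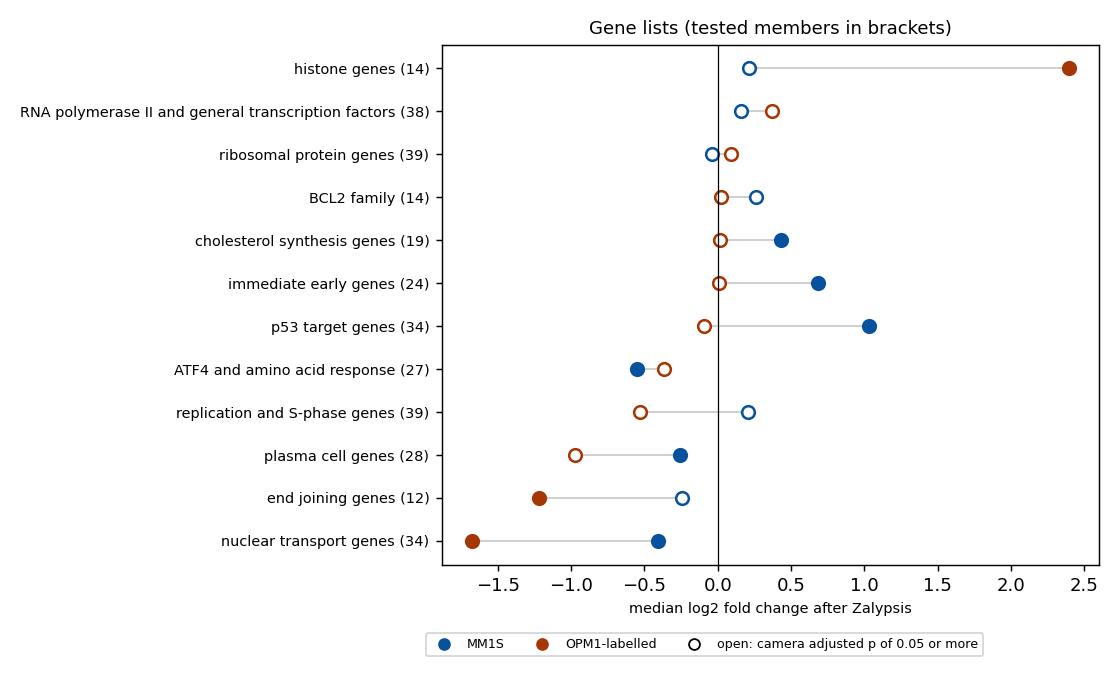
Median log2 fold change of each gene list after Zalypsis (x axis, log2(value + 32)) in MM1S and in OPM1-labelled cells, with the number of tested members in brackets. Filled points have a camera adjusted p under 0.05 at the preset correlation. The p53 target genes lie at 1.03 in MM1S and -0.10 in OPM1-labelled cells, and histone genes reach 2.39 in the latter.

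The lines shared a large part of the response. HEXIM1 rose in both (log2 2.56 in MM1S and 2.62 in OPM1-labelled cells), as did SERTAD1 (2.53 and 2.49), MARCKSL1 (2.14 and 2.67), SAT1 (1.86 and 2.16), an enzyme of polyamine breakdown, and TOB1 (1.83 and 2.66), an antiproliferative factor. RNA45SN5, a precursor of ribosomal RNA, rose by 1.81 and 2.44. With the poly-A scaling, the rises of HEXIM1 (log2 0.56), MARCKSL1 (0.58), SAT1 (0.07), TOB1 (0.59) and RNA45SN5 (0.39) in OPM1-labelled cells were not called. TIAM1 fell in both (log2 -3.73 and -3.60), as did CAMK1D (-3.62 and -3.47), PRKCA (-3.45 and -3.52), SCFD2 (-3.40 and -3.67), FTO (-3.37 and -3.45) and UBE2E2 (-3.37 and -3.36). These 6 fallen genes span a median of 463 kb of the genome and the 6 risen ones 4.01 kb, against 28.3 kb for all tested genes. The calls overlapped by 1133 genes higher in both lines, where independent lists would share 495, and by 2087 lower in both, where they would share 965. Those higher in both numbered 603 without MM1S Zalypsis 1 and 709 without MM1S control 2. Only 220 genes were higher in MM1S and lower in OPM1-labelled cells, and 51 the reverse, where 751 and 636 would be shared. Fold changes of the lines correlated across genes at r = 0.640 and rho = 0.626, and genes are not independent replicates. Of the 3220 genes called the same way, 64.8% were lower, and 49.1% after quantile normalization. With the poly-A scaling 1518 were called the same way and 98.5% of them were lower, so that few rises were shared.

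The response differed between the lines in 5524 of 11865 genes by the interaction test, with OPM1-labelled cells higher in 1821 and lower in 3703. The largest difference among genes of interest was that of CDKN1A, which rose in MM1S and fell in OPM1-labelled cells (log2 -3.71 ± 0.23, adjusted p = 6.4e-11), and MDM2 behaved likewise (-3.26 ± 0.22, adjusted p = 1.8e-10). MYC fell in both, and more in OPM1-labelled cells (-1.76). Of the 34 p53 target genes 22 responded lower in OPM1-labelled cells and 2 higher (23 and 2 over the list alone), with a median difference of -0.90 (camera adjusted p = 1.4e-04, adjusted p = 0.988 with an estimated correlation). PLK2 (-2.24), which lay at 6.45 ± 3.46 in untreated OPM1-labelled cells, and TRIM22 (-2.03) were among them. Lower responses made up 67.0% of the calls, and 52.4% after quantile normalization. With the poly-A scaling 10684 responses differed and 98.4% of them were lower.

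The largest differences toward OPM1-labelled cells were in FBXL7 (log2 3.64), CADPS2 (3.43), DOCK4 (3.40), ROBO1 (3.21) and ARHGAP6 (3.21). All 5 were above 400 in MM1S controls and below 20 in OPM1 controls, so only MM1S had a signal to lose. TLCD2 (3.25) rose from 14.8 ± 1.33 to 440 ± 68.0 in OPM1-labelled cells. The largest the other way were in PAX5 (-5.27), ID3 (-5.00), RUBCNL (-4.67), BEST3 (-4.39), RGS13 (-4.02) and PPM1E (-3.95). Of these, ID3 had a signal of 113 ± 12.2 in MM1S controls and the others lay below 40.

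Histone genes responded higher in OPM1-labelled cells, 10 of 14 with 0 lower, the same over the list alone (median difference 1.71, camera adjusted p = 5.2e-08, adjusted p = 0.230 with an estimated correlation), with H2BC5 (2.82), H2BC6 (2.74), H2AC6 (2.57) and the linker histone gene H1-2 (2.55). Of 39 replication and S-phase genes 24 responded lower and 0 higher (25 and 0 over the list alone, median -0.75, camera adjusted p = 1.7e-03, adjusted p = 0.988 with an estimated correlation). CDC45 (-2.75), UHRF1 (-1.96), MCM3 (-1.93) and GINS1 (-1.90) led them. Of 34 nuclear transport genes 26 responded lower and 2 higher (27 and 2 over the list alone, median -1.32, camera adjusted p = 5.6e-05, adjusted p = 0.988 with an estimated correlation), led by CSE1L (-2.65), KPNA3 (-2.14) and NUP107 (-2.01), with NUP205 next. Of 12 end joining genes 8 responded lower and 0 higher, the same over the list alone (median -0.85, camera adjusted p = 0.0134, and 0.0692 with the poly-A scaling, adjusted p = 0.988 with an estimated correlation), with DCLRE1C (-2.39), LIG4 (-1.78), PRKDC (-1.73) and XRCC5 (-1.70). XRCC5 was not called without probe sets shared between transcripts (-0.19, adjusted p = 0.406). In the ATF4 list 9 of 27 genes responded higher and 5 lower, the same over the list alone (median 0.11, and -1.69 with the poly-A scaling, camera adjusted p = 7.6e-03, adjusted p = 0.988 with an estimated correlation), with SLC7A11 (2.73) and CHAC1 (2.58) higher and STC2 (-1.82) lower. SESN2 (1.90) turned to -0.017 with that scaling. Ribosomal protein genes had a median difference of 0.15, with 9 of 39 higher and 1 lower (7 and 0 over the list alone, camera adjusted p = 4.2e-03, adjusted p = 0.988 with an estimated correlation), which turned to -1.95 with the poly-A scaling and had a camera adjusted p of 0.153 after quantile normalization. RPS9 (0.86), RPS25 (0.82), RPS24 (0.77) and RPL18 (0.76) led them, and all 4 turned negative with the poly-A scaling. RPL18 lost its call in 11 other settings and RPS9 in 4, and RPS24 was at -0.015 without shared probe sets.

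Untreated OPM1-labelled cells differed from untreated MM1S cells in 7563 of 11865 genes, 3390 higher and 4173 lower, and 2968 of them by over 2-fold. Lower genes made up 55.2% of the calls, and 48.4% after quantile normalization. The plasma cell genes SDC1, IL6R and CD28 were near background in OPM1-labelled cells, where the B-cell genes PAX5 and CD79A were bright. JCHAIN, which encodes the joining chain of immunoglobulins, was dimmer than in MM1S but present, at 2031 ± 232 against 10641 ± 95.1, and so was IRF4, at 318 ± 46.5 against 4383 ± 727. MAF, a transcription factor overexpressed in some myelomas, had a signal of 4668 ± 68.4 in MM1S and 5.69 ± 2.96 in OPM1-labelled controls (log2 -6.96, adjusted p = 1.4e-19), and CCND2, which encodes cyclin D2, 5667 ± 502 and 8.20 ± 2.50 (-7.15, adjusted p = 1.4e-19). FGFR3 was dim in both, at 35.5 ± 8.81 and 23.9 ± 4.26, and was not called (-0.27, adjusted p = 0.11). NSD2 was lower in OPM1-labelled cells (-1.17, adjusted p = 8.1e-07). The poly-A control signals were higher on all OPM1 arrays, but genes such as IGHM and MAF differed in opposite directions and by more, and the hybridisation controls were alike. Smaller differences between the lines may include effects of labelling.

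The immunoglobulin gene IGHM was the most raised in OPM1-labelled controls, at 5792 ± 1875 against 13.5 ± 5.03 (log2 6.97), followed by TCL1A (6.86), ZNF595 (6.62), RUBCNL (6.59), PAX5 (6.38) and MLLT11 (6.22). The largest differences the other way were in the light chain gene IGLL5 (-7.22), CCND2, the adhesion receptor gene CD44 (-7.14), MAF, IL6R (-6.35), which encodes a chain of the interleukin 6 receptor, and QPCT (-6.34). Of 28 plasma cell genes 24 were lower and 4 higher, the same over the list alone (median -2.13, camera adjusted p = 3.5e-06, adjusted p = 0.909 with an estimated correlation). SDC1, which encodes the plasma cell marker CD138, lay at 2946 and 3443 on the MM1S and at 6.56 and 12.9 on the OPM1-labelled control arrays (log2 -6.27), and CD28 was lower too (-4.96). CD79A, a chain of the B-cell receptor complex, was higher, at 3279 ± 221 against 19.7 ± 3.58. Of 9 translocation and cyclin genes of myeloma 6 were lower and 2 higher, the same over the list alone (median -1.17, camera adjusted p = 0.0213, adjusted p = 0.909 with an estimated correlation), with ITGB7 (-6.31) and IRF4 (-3.65) next to CCND2 and MAF.

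Of 29 genes of the unfolded protein response 25 were lower in OPM1-labelled controls and 1 higher, the same over the list alone (median -1.14, camera adjusted p = 1.0e-05, adjusted p = 0.909 with an estimated correlation), among them PDIA4 (-2.63), HERPUD1 (-2.47), SEL1L (-2.45) and MANF (-2.41). Of 40 genes of G2 and mitosis 34 were lower and 1 higher (35 and 1 over the list alone, median -0.89, camera adjusted p = 1.0e-05, adjusted p = 0.909 with an estimated correlation), with MKI67 (-2.79), ASPM (-1.77), KIF23 (-1.68) and DLGAP5 (-1.64). Of 19 cholesterol synthesis genes 15 were lower and 2 higher, the same over the list alone (median -0.92, camera adjusted p = 5.4e-03, adjusted p = 0.909 with an estimated correlation), with INSIG1 (-3.45), MSMO1 (-2.24), LSS (-1.77) and HMGCS1 (-1.77). Interferon-stimulated genes were higher in OPM1-labelled controls, 17 of 27 against 5 lower, the same over the list alone (median 0.75, camera adjusted p = 6.0e-03, adjusted p = 0.909 with an estimated correlation). ISG15 (3.45), MX2 (2.84) and IFITM1 (2.73) were higher and HERC5 (-3.99) lower.

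**Figure D4:**
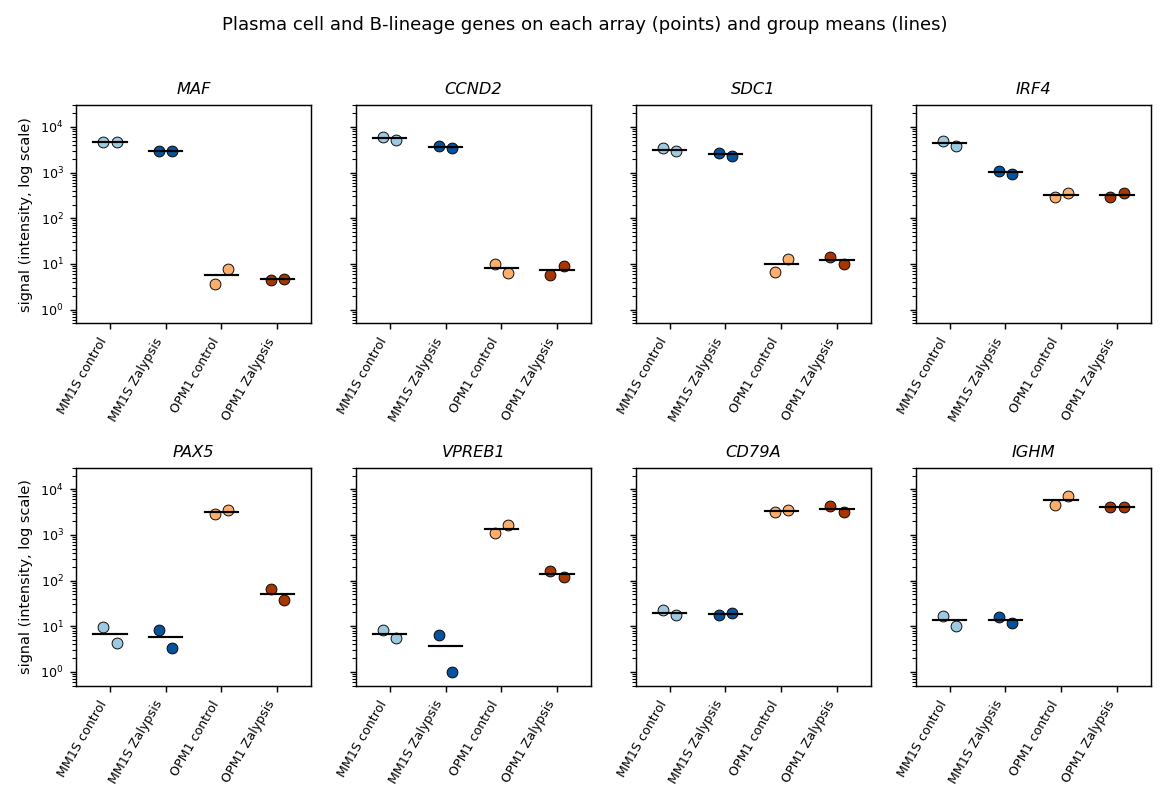
Signals (log axis, intensity) of MAF, CCND2, SDC1, IRF4, PAX5, VPREB1, CD79A and IGHM on each array. Points are arrays, 2 per group, and lines are group means. SDC1 averages 3194 in MM1S and 9.71 in OPM1-labelled controls, and PAX5 6.89 and 3219.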

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

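The tests of the control probe sets below were chosen after their rise had been seen. The comparison of responses was planned.

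The response to Zalypsis differed between the lines in 5524 genes by the interaction test, with the opposite directions of CDKN1A (log2 -3.71) and MDM2 (-3.26) and the deeper fall of MYC in OPM1-labelled cells (-1.76) among them. The largest differences toward OPM1-labelled cells were those of FBXL7 (3.64), CADPS2 (3.43), DOCK4 (3.40), TLCD2 (3.25), ROBO1 (3.21) and ARHGAP6 (3.21). Those toward MM1S were PAX5 (-5.27), ID3 (-5.00), RUBCNL (-4.67), BEST3 (-4.39), RGS13 (-4.02) and PPM1E (-3.95). Most of these 12 genes had a signal in only 1 of the untreated lines. The lists differed in their medians by 1.71 for histone genes, 0.11 for the ATF4 and amino acid response and 0.15 for ribosomal protein genes. Toward MM1S they differed by -1.32 for nuclear transport, -0.90 for p53 target genes, -0.85 for end joining and -0.75 for replication and S-phase genes. None of these list calls held with an estimated correlation (lowest adjusted p = 0.230), and the poly-A scaling turned the medians of the ATF4 and ribosomal lists to -1.69 and -1.95.

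In OPM1-labelled cells the 4 poly-A control probe sets rose by a median of 2.23 on the log2 scale after Zalypsis, and the 6 ribosomal RNA probe sets by 1.49. Brighter arrays alone would raise the 9 hybridisation controls as well, but these rose by only 0.16. More control RNA in the treated samples would not raise ribosomal RNA, but it cannot be excluded as a source of the poly-A rise: between the untreated lines the poly-A controls differed by 3.97 and ribosomal RNA by only 0.13. The size of 3.97 is uncertain, because it rests partly on signals near background. In MM1S controls the lys, phe and thr probe sets averaged 9.85, 15.1 and 10.1, and only dap was brighter, at 101. A smaller share of messenger RNA in the total RNA would raise both kinds, and their rises of 2.23 and 1.49 are in line with that. The measure of messenger RNA per cell that would test this was not made here, so both explanations stay open. If messenger RNA was lost, many genes counted as unchanged may have fallen.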

How the results depend on the processing

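The scaling by poly-A controls was added after the data were seen, and the other settings were planned. With every probe set tested, 7929 were called in MM1S, 14270 in OPM1-labelled cells, 9520 for the difference, 13993 between the untreated lines and 5733 in both lines, because more probe sets than genes were tested. A cutoff of a change over 2-fold, as in the authors' rule, gave 1043, 3528, 2519, 2968 and 759 in the same order. These counts were the same with or without the test. The cutoff was applied to the log2 values with the pseudocount, in the genes that passed the filter. The pseudocount shrinks the changes of dim genes, so dim genes may be missing from these counts. The authors' rule on the deposited intensities was not tested. The poly-A scaling gave 10684 differences between responses, 98.4% of them lower, and 1518 genes in both lines, 98.5% of them lower. It lowers every gene on the treated OPM1 arrays, which moves these shares toward lower. That removes shared rises, of which there were 1133 among the 3220 shared calls without the scaling. It does not explain fewer shared falls, yet all 1518 shared calls were fewer than the 2087 shared falls without it. The scaling also shifted arrays of a group unequally, by log2 0.290 and -0.290 for OPM1 controls and -2.35 and -1.88 for treated arrays. All groups share 1 spread, and whether this cost calls was not tested. Leaving out MM1S Zalypsis 1 or MM1S control 2 left 986 or 1163 genes higher in MM1S and 603 or 709 higher in both. Leaving out any 1 array gave 3137 to 4772 calls in MM1S, 6773 to 7621 in OPM1-labelled cells, 4826 to 5506 differences, 6785 to 7442 between the untreated lines and 2392 to 3278 in both.

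Of 3563 values for 181 named results, 3519 kept their call and direction, 36 lost the call and 8 reversed. Some settings, such as other variance models, leave the log2 change as it is, so no direction could reverse there. Many named genes had also been picked for their large changes, which makes a lost call less likely. SC5D in MM1S reversed without shared probe sets (log2 -0.0016), and so did RPS24 for the difference (-0.015). TRIAP1 in OPM1-labelled cells (-0.30) reversed with the poly-A scaling, as did the differences of SESN2 (-0.017), RPS9 (-1.24), RPS25 (-1.27), RPS24 (-1.33) and RPL18 (-1.34). For the shared probe sets the cause was not tested.

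With the replicate number as a block, 5461 genes were called in MM1S, 8101 in OPM1-labelled cells, 6344 for the difference and 3900 in both lines. As a pairing check, the log2 difference between replicates 1 and 2 was compared across genes between controls and treated arrays. These differences correlated at 0.212 in MM1S and 0.209 in OPM1-labelled cells, with only 2 pairs per line.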

Other observations

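The tests of cell identity, the marker list they use, the comparison with genes of like signal and the split by signal were chosen after their results or related ones had been seen, and the tests of gene span before.

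Of 20 tested B-lineage markers, 16 fell in OPM1-labelled cells after Zalypsis and 1 rose, on arrays where the poly-A control and ribosomal RNA signals rose as well. The markers were listed after PAX5 and others had been seen to be bright in these cells, so most had a signal to lose. Of the genes nearest to them in control signal, 50 for each marker, 52.5% were called lower, against 38.5% of all 11865 tested genes. EBF1 went from a signal of 512 ± 27.0 to 11.8 (log2 -3.63), BACH2 from 924 ± 56.2 to 7.78 (-4.59) and MYB from 3321 ± 54.2 to 119 (-4.48), all as means of 2 arrays. TCL1A fell by 3.17 and CD24 by 3.61 on the log2 scale. CD79A, a surface receptor component, was not lower (0.17), and the transcription factor gene SPIB was higher, from 246 to 499 (log2 0.93).

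Genes that cover long stretches of the genome were lower after Zalypsis in both lines. The rank correlation of span with the log2 change was -0.48 in MM1S and -0.48 in OPM1-labelled cells. It was -0.31 in the latter with the poly-A scaling, and -0.33 in both lines with no filter on low values. The 8 largest falls in MM1S spanned a median of 460.5 kb, against 5.50 kb for the 8 largest rises. A signal effect would remove the trend among genes of like signal, but the weakest correlation within 1 of 5 bins of the signal was -0.26. A length bias that differed between the lines' arrays would show between the untreated lines, where the correlation was 0.00404. A bias shared by all arrays cancels in that comparison, and one tied to the treated RNA is absent from it. Neither can be excluded by this value.

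A loss of transcript that grows with span, as when polymerase stops on the way, would lower each longer class more, but only 6 of 8 steps went down, so the test failed. The medians were -0.70 for genes of 100 to 300 kb and -0.59 above that in MM1S, and -1.24 and -0.32 in OPM1-labelled cells. Among brighter genes, a split tried once after this failure, the longest class was at -1.36 and -2.07, against -0.91 and -2.04 for the next, but it held only 43 genes, and fewer of them were called lower (74.4% against 79.1% in MM1S, 76.7% against 89.4% in OPM1-labelled cells). The medians of these brighter genes fell at each step in both lines, but the share called lower did not rise at the last. Because the split followed the failure, it does not replace the failed test. With the trend on span removed, the median of the nuclear transport list in OPM1-labelled cells went from -1.68 to -0.97. That loss was smaller than the one set beforehand for span as the explanation, so this test failed too. Why the longest genes broke the order may lie in their low signal, which a test with 6 of 8 steps down cannot separate from a limit of the effect itself.

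Some plasma cell transcripts were near background on the OPM1-labelled arrays, SDC1 among them, while JCHAIN (2031 in controls) was present. A swap of some arrays between the lines would put an array on the other line's side for MAF, CCND2 or SDC1, and 0 arrays were there, which leaves an exchange of all arrays of both lines untested. Of the 20 tested B-lineage markers 18 were higher in the untreated cells, but as the list was made after some of them had been seen, this describes the difference and does not test whether the cells are of an earlier stage. A mixture with plasma cells cannot be told from these data, since the highest SDC1 signal on an OPM1-labelled array was 0.589% of the lowest on an MM1S array but the line's own level is not known here. The identity of these cells stays open.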
